A study of Homo sapiens and Mus musculus with 4 samples.

How the data were processed

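ATF4 binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in 2 cell sources. One was KG1a, a human acute myeloid leukaemia cell line grown in medium with 20% serum. The other was bone marrow cells of C57BL/6 mice. Each source had 1 library precipitated with an anti-ATF4 antibody and 1 input library of the same chromatin taken without antibody, so the 4 libraries form 4 groups of 1. ATF4 is a transcription factor that is produced when translation is slowed by amino acid shortage or other stress.

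The libraries were sequenced on an Illumina instrument, per the labels' protocols. Per the submitters' processing notes, CASAVA 1.4, Bowtie2, MACS2 and deepTools were used and the builds were GRCh38 and GRCm38. Those notes, as used here, do not say which setting or peak threshold was applied, and the peak caller's threshold is not given in the sources used here. The labels name 1 list per cell source, made from the ChIP library against its input. The deposited lists have 3 columns, which hold the chromosome and the start and end position of each peak in bases. They carry no peak height, fold enrichment, p-value or summit. Read numbers, sequencing depth and the signal of the input libraries were not analysed here, so the depth is unknown and no precision can be given for a single peak. A list reflects both the strength of binding and the number of reads behind it. Starts were read as counted from 0, the convention of this file type, and are printed counted from 1. The centre of a peak was taken as the middle of its interval.

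KG1a peaks were placed against a table of RefSeq genes of the assembly GRCh38.p14, which shares its chromosome coordinates with GRCh38. The table gives the chromosome, start and end of each gene but no strand, exons or sequence. Which end of a gene is its transcription start was therefore not used, and distances were measured to the nearer of the low-coordinate and the high-coordinate end. The 20037 protein-coding genes on the numbered chromosomes, X and Y were used. A gene was counted as having a peak where a peak centre lay within 1 kb of either end, and a peak between neighbouring genes counted for each. The design set before the data were examined had foreseen transcription start sites, peak scores, searches for the ATF4 binding sequence and other motifs, and mouse genes. Start sites need the strand of each gene, scores a further column in the lists, motifs a genome sequence and mouse genes a mouse annotation. None of these was used here, so the motif tests, the mouse gene assignments, the overlap of genes between the lists and the comparison of motif enrichment between the lists were not run.

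The share of peaks near a gene end and inside a gene was compared with 1000 random placements of the same number of peaks on each chromosome, between the first and the last protein-coding gene, with a two-sided permutation test. Its smallest possible p is 0.002. Assembly gaps could not be left out of the placements. Intervals on shares are Wilson 95% intervals and cover counting error only. Neighbouring peaks are not independent, and with no replicate libraries analysed here each p describes the deposited list and not the variation between cultures or animals. Gene lists, 15 in all with 238 different genes, were fixed before the data were examined. All of their symbols were found in the gene table. Each list was compared with all 20037 genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 15 lists. Chromosome totals were compared with chromosome length, taken as the highest position of a protein-coding gene for KG1a, by exact binomial tests with the same adjustment over 23 chromosomes. For the mouse list the length was taken as the highest peak position on the chromosome. Spacing between neighbouring peaks was compared with 100 random placements.

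The genes named were set by a rule fixed before the data were examined. It takes the protein-coding genes nearest to the 15 highest-scoring peaks, every member of a fixed list with a KG1a peak within 1 kb of an end, and 10 genes named whatever their result. As the lists hold no score, the 15 widest peaks were used. The alternatives were other distances (500 bp, 5 kb, the nearest gene within 50 kb), the widest 25% of the list, and autosomes alone. Others were chosen after the data were seen. They were shifts of each peak by up to 500 kb in place of random placement, the first 25% of the list in its deposited order, peaks inside genes, and 10000 random lists matched on gene length. The code was tested on simulated data. In 20 simulated lists with 60 peaks planted at gene ends among 869 random peaks, the excess was detected in 20, and a gene list with 5 planted members was detected in 20. In 20 lists without planted peaks neither the share nor a gene list was called, which is 0 calls of each. Lists with fewer planted members were not simulated, although the calls below for amino acid synthesis and stress response genes rest on 2 members each. The lists without planted peaks lay near gene ends less often than the real peaks, so they give no rate of false gene list calls for the real list. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.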

Results

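The series holds 1 list of ATF4 peaks for KG1a cells and 1 for mouse bone marrow cells, each from 1 ChIP library against 1 input library. No replicate libraries were analysed here. The KG1a list had 873 peaks, of which 869 lay on chromosomes. The mouse list had 83088 peaks, of which 82993 lay on numbered chromosomes, X or Y. Read depth was not part of the lists.

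The first comparison was KG1a ATF4 ChIP against KG1a input, which asks where ATF4 sat on the genome of these leukaemia cells. Among the 102 protein-coding genes with a peak within 1 kb of an end were a few that charge tRNAs, make amino acids or respond to stress. The 4 cytosolic tRNA synthetase genes AARS1, GARS1, TARS1 and YARS1, which encode the enzymes for alanine, glycine, threonine and tyrosine, each had a peak within 1 kb of a gene end. So did MTHFD2, a mitochondrial one-carbon enzyme, and GPT2, a mitochondrial alanine transaminase. CHAC1, an enzyme that degrades glutathione, HERPUD1, a protein of endoplasmic reticulum protein degradation, and SLC7A11, the light chain of the cystine and glutamate exchanger, also had one. No listed peak lay at ASNS, DDIT3, TRIB3 or PSAT1, which are widely used as ATF4 target genes.

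Peaks were found near gene ends more often than random positions. The centre of 89 of the 869 peaks, 10.2% (Wilson 95% interval 8.40 to 12.4%), lay within 1 kb of an end of a protein-coding gene, against 2.59% for random placements. The ratio was 3.96 (two-sided permutation test, p = 0.002, the smallest that 1000 placements can give). These peaks touched 102 of 20037 protein-coding genes, or 0.509%. Inside protein-coding genes lay 436 peaks, 50.2%, against 42.6% for random placements (ratio 1.18, permutation p = 0.002). This second excess was not past the threshold when each peak was shifted by up to 500 kb, which keeps it in its own neighbourhood (ratio 1.04, permutation p = 0.27), or in the widest 25% of the list (ratio 1.11, permutation p = 0.20).

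Genes of tRNA charging known as ATF4 targets held the largest share of members with a peak. This list holds synthetase genes and XPOT, which encodes an exporter of tRNA and had no listed peak within 1 kb. In it 4 of 13 genes had a peak within 1 kb, where 0.0662 were expected from all protein-coding genes (Fisher's exact test, adjusted p = 6.6e-06). The AARS1 peak spanned chromosome 16, 70289309 to 70289847 (GRCh38, as are all KG1a positions here), with its centre 72 bp outside the high-coordinate end of the gene and within 1 kb of its neighbour DDX19B. The YARS1 peak spanned chromosome 1, 32817100 to 32817646, and its centre lay 15 bp outside the high-coordinate end, a position within 1 kb of S100PBP as well. The GARS1 peak, on chromosome 7 from 30594701 to 30595147, was centred 189 bp inside the low-coordinate end. The TARS1 peak, on chromosome 5 from 33440834 to 33441185, was centred 313 bp inside the low-coordinate end. Of the 8 other cytosolic synthetase genes, 0 had a peak within 1 kb. With 0.0407 expected there, a list of that size cannot show a deficit, and the difference between both synthetase lists was not tested.

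**Figure D1:**
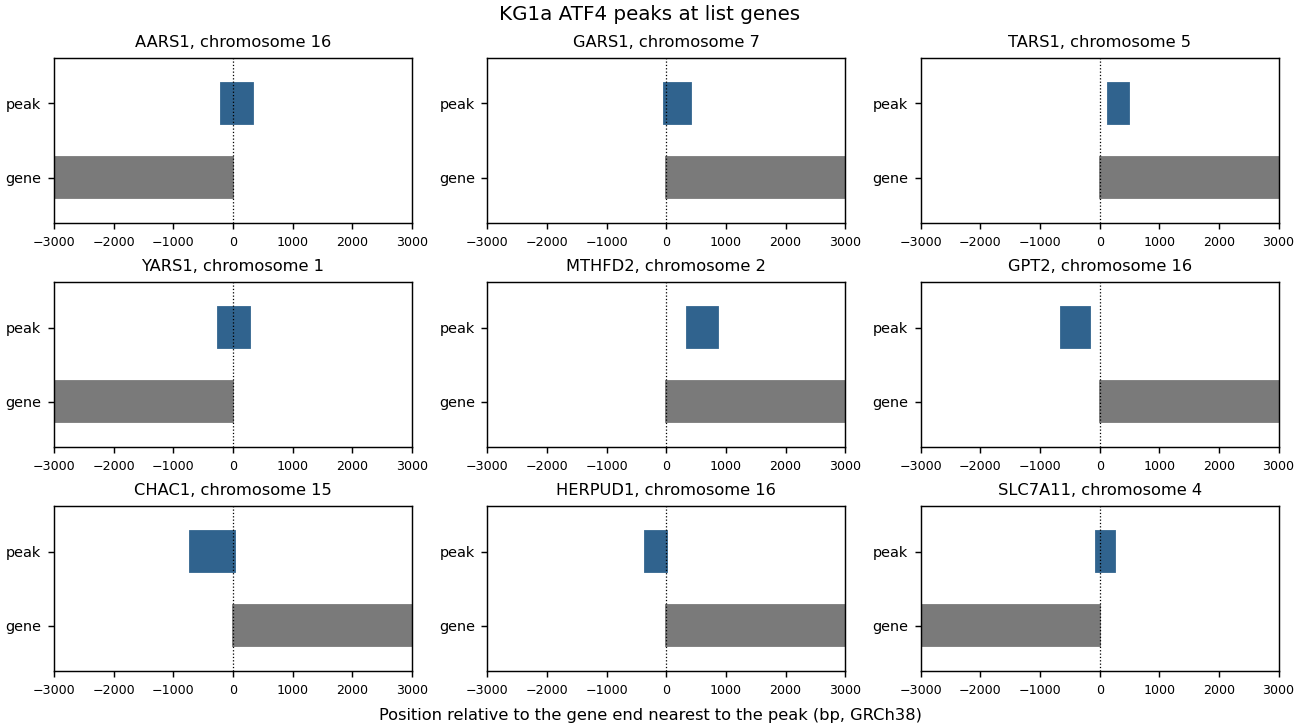
Each panel shows 1 gene (grey) and its KG1a ATF4 peak (blue) on GRCh38, with the horizontal axis giving the position in bp relative to the gene end nearest to the peak, drawn to scale. The AARS1, GARS1, YARS1, CHAC1, HERPUD1 and SLC7A11 peaks cross the gene end, the TARS1 and MTHFD2 peaks lie inside it, and the GPT2 peak lies outside.

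Amino acid synthesis and one-carbon genes followed, with 2 of 13 members against 0.0662 expected (Fisher's exact test, adjusted p = 0.014). The MTHFD2 peak spanned chromosome 2, 74198970 to 74199483, centred 611 bp inside the low-coordinate end. The GPT2 peak spanned chromosome 16, 46883708 to 46884198, centred 409 bp outside the low-coordinate end. This list's call rests on 2 genes and was not past the threshold within 500 bp, where MTHFD2 dropped out (Fisher's exact test, adjusted p = 0.17). Nor was it past the threshold when each peak was given to its nearest gene within 50 kb (adjusted p = 0.15) or when peaks inside genes were counted (adjusted p = 0.12, both by Fisher's exact test). Within the list, the nearest listed peak lay 1.48 Mb from ASNS, the asparagine synthetase gene, and 754 kb from PSAT1, a gene of serine synthesis.

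Stress response regulators had 2 of 21 members with a peak against 0.107 expected (Fisher's exact test, adjusted p = 0.025). The CHAC1 peak was 753 bp wide, on chromosome 15 from 40952753 to 40953505, with its centre 342 bp outside the low-coordinate end. The HERPUD1 peak spanned chromosome 16, 56931777 to 56932161, centred 173 bp outside the low-coordinate end. For DDIT3, which encodes the stress factor CHOP, the nearest listed peak lay 7.09 Mb away, and for TRIB3, a pseudokinase gene, 58.3 kb away. VEGFA, a growth factor gene counted in both the stress and the hypoxia list, had its nearest peak 45.0 kb outside the gene, at chromosome 6, 43725053 to 43725430.

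Amino acid transporters had 1 of 10 members with a peak, SLC7A11 (Fisher's exact test, adjusted p = 0.19), at chromosome 4, 138242289 to 138242604, centred 97 bp outside the high-coordinate end. Hypoxia and glycolysis genes had 1 of 19 (Fisher's exact test, adjusted p = 0.24). That gene was PFKFB4, which encodes a regulator of glycolysis, with a peak 682 bp outside its high-coordinate end at chromosome 3, 48563662 to 48563975. COL7A1 and UCN2 lie within 1 kb of the same peak. HIF1A, the gene of the oxygen-sensing factor, had no peak nearer than 2.02 Mb. The list of genes of other tissues, a control, also had 1 of 20 (Fisher's exact test, adjusted p = 0.24). Its member was APOA1, an apolipoprotein gene, with a peak inside the gene 894 bp from the high-coordinate end, at chromosome 11, 116836555 to 116836901.

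Lists for blood stem cells and blood lineages held no gene with a peak within 1 kb. These were 0 of 20 stem cell regulators, 0 of 18 genes of stem cell ageing, 0 of 13 myeloid, 0 of 11 erythroid and 0 of 16 lymphoid markers. Autophagy (0 of 14), mitochondrial proteostasis and antioxidant genes (0 of 19) and ribosomal protein genes, a control of active promoters (0 of 25), also held none. Fewer than 1 member was expected in each of these lists, so the counts cannot show a deficit. GATA2, a stem cell transcription factor gene, lay 1.75 Mb from its nearest peak, and the ATF4 gene itself lay 372 kb from its nearest peak.

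**Figure D2:**
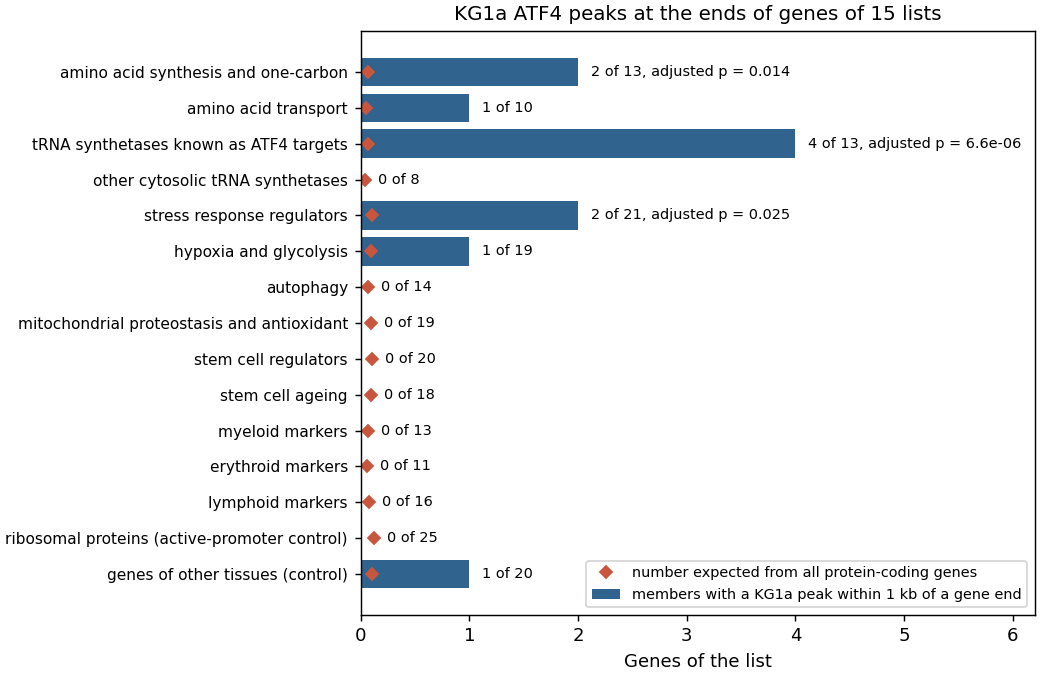
Bars give the number of genes of each of 15 fixed lists with a KG1a ATF4 peak centre within 1 kb of a gene end, and diamonds give the number expected from all protein-coding genes. The list of tRNA synthetases known as ATF4 targets, which also counts the tRNA exporter XPOT, stands highest with 4 of 13 members, and 9 lists have 0.

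Of the 15 widest KG1a peaks, 14 lay on chromosomes and 4 of these lay within 1 kb of a gene end. In the widest 25% of the list the share was 16.2%, or 5.93 times that of random placements (permutation p = 0.002). The widest, 1183 bp, covered the high-coordinate end of EEF1A1, which encodes a translation elongation factor, at chromosome 6, 73520043 to 73521225. CHAC1, C18orf32 and CTNNA3 were the other genes with one of these peaks within 1 kb, at 342, 35 and 847 bp. The second widest, 1023 bp, lay 13.0 kb from KLHDC4, and further wide peaks lay 5.89 kb from CYP1A2, 49.4 kb from TCF3, 42.2 kb from CRYBA4, 6.68 kb from TMEM239 and 4.38 kb from WNT11. AGBL2 and IQSEC1 had wide peaks inside the gene, 11.4 and 115 kb from the nearer end. Those nearest to BCHE and NUF2 lay 307 and 431 kb away, and 1 of the 15 fell on an unplaced scaffold. Of all 873 peaks, 148 overlapped a long non-coding RNA gene and 3 a tRNA gene. These overlaps were not compared with random placements, so they show no excess or deficit.

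KG1a peaks were unevenly spread over chromosomes. Of 23 chromosomes tested, 4 differed from the number their length gives. Chromosome Y held no KG1a peak and was not among those tested. Chromosome X had 9 peaks where 44.8 were expected (ratio 0.20, exact binomial test, adjusted p = 2.1e-09), and chromosome 5 had 25 where 52.1 were expected (ratio 0.48, adjusted p = 0.00035). Chromosomes 11 and 19 had more, with 56 against 38.6 (adjusted p = 0.037) and 29 against 16.8 (exact binomial test, adjusted p = 0.037). All expected numbers share the same total of peaks, so the low numbers on X and 5 by themselves push other chromosomes above theirs. Whether 11 and 19 differ with X and 5 left out was not tested. A further count, which the design had not foreseen, took only peaks farther than 5 kb from a gene end. There chromosome 11 had 36 against 30.9 (p = 0.36) and chromosome 19 had 17 against 13.5 (p = 0.33, both by exact binomial test, unadjusted). These expected numbers used the whole chromosome length, including the stretches within 5 kb of gene ends, so they are too high on a gene-dense chromosome. The count therefore cannot decide whether the excess on both extends away from gene ends.

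The second comparison was mouse bone marrow ATF4 ChIP against its input, which asks the same of primary blood-forming tissue. The mouse peaks were many, wide and grouped. They covered 76.0 Mb, with a median width of 544 bp, an interquartile range of 361 to 974 bp and a longest peak of 17247 bp. Wider than 2 kb were 7793 peaks, 9.38% of the list. The widest ran on chromosome 5 from 117020303 to 117037549 (GRCm38), followed by one of 16707 bp on chromosome 18 from 72377072 to 72393778. A pair of 16597 and 16350 bp stood close together on chromosome 17, from 26387098 to 26403694 and from 26303669 to 26320018. Gene names were not assigned to mouse peaks.

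Mouse peaks clustered along chromosomes. Neighbouring peak centres lay a median of 8.46 kb apart, against 20.6 kb for random placements. Of neighbouring pairs, 36.9% lay within 3 kb of each other, against 9.68% at random (permutation test, p = 0.020, the smallest that 100 placements can give). In KG1a, with 846 neighbouring pairs, the same share was 0.355% against 0.109% at random (permutation p = 0.099). So few pairs lay that close that this test cannot show whether KG1a peaks cluster. The densest mouse window of 1 Mb, on chromosome 5 from 137 to 138 Mb, held 129 peaks, where the median window held 30. Windows from 133 to 134 Mb and from 119 to 120 Mb on the same chromosome held 115 and 111, and the window from 165 to 166 Mb on chromosome 2 held 112.

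Peak density differed between mouse chromosomes. It was 43.2 peaks per Mb on chromosome 11 and 40.0 on chromosome 5, and 25.7 on chromosome 3, the lowest of the 19 autosomes. Chromosome X had 1577 peaks, or 9.28 per Mb, which is 0.28 of the 33.1 per Mb of the autosomes together. The Y chromosome had 119 peaks.

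**Figure D3:**
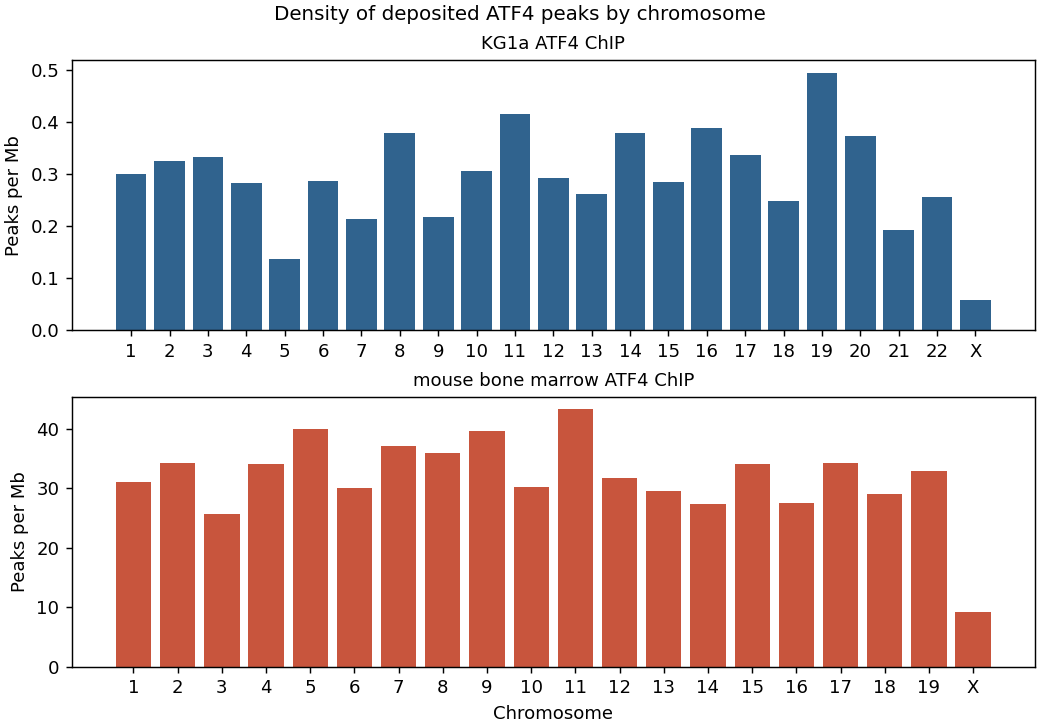
Bars give the number of deposited ATF4 peaks per Mb on each chromosome, for KG1a (upper panel) and mouse bone marrow (lower panel), with separate linear axes from 0 and without Y. Chromosome X has the lowest density in both, at 0.058 and 9.28 peaks per Mb.

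Set side by side, the lists differed in the number of peaks far more than in median peak width. The mouse list had 95.2 times as many peaks as the KG1a list and covered 239 times as many bases, 76.0 against 0.318 Mb. The median width was 544 bp in mouse and 341 bp in KG1a. Most KG1a widths lay close to their minimum of 310 bp, with an interquartile range of 323 to 371 bp. Wide peaks differed far more than the median, as 24.2% of mouse peaks but 0.229% of KG1a peaks were wider than 1 kb. With 1 ChIP library per source, unknown depth and different species, these differences have no replicate check and no test between the sources was made. No peak can be called lost or gained between them.

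**Figure D4:**
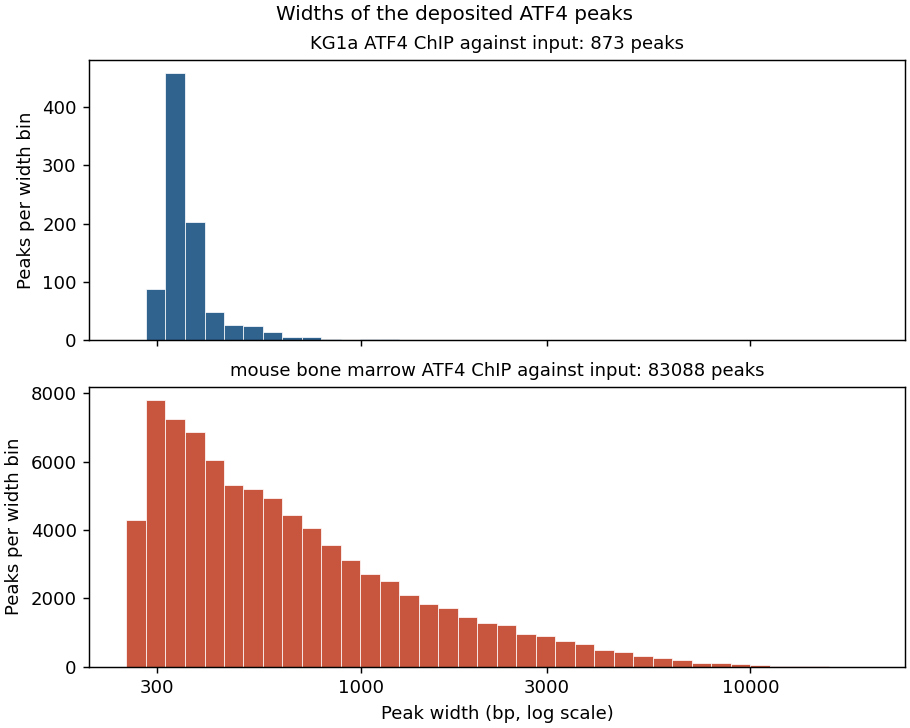
Histograms of peak width in bp on a log axis, with the number of peaks per width bin on the vertical axes, for KG1a (upper panel) and mouse bone marrow (lower panel). KG1a widths run from 310 to 1183 bp and mouse widths from 265 to 17247 bp.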

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

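The questions about the deposited order of the list and about scaffolds were raised after the data were seen. For the order, both tests were fixed before their own results were known.

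The order in which the KG1a peaks were deposited carries a signal, although the file names no score. Of the first 25% of the list, 18.2% of peaks (39 of 214 on chromosomes) lay within 1 kb of a gene end, against 7.63% (50 of 655) of the rest (Fisher's exact test, p = 2.6e-05). Of the 11 genes of the fixed lists with a peak, 9 had it in the first 25%, among them CHAC1 in place 7, YARS1 in place 8, GPT2 in place 12 and AARS1 in place 13 of 873. Peak width is argued against as the whole cause. Among peaks at or under the median width, the share was 13.9% in the first 25% and 6.63% in the rest (Fisher's exact test, p = 0.038). That the later peaks are no nearer to gene ends than random positions is also argued against. In the last 50% of the list the share was 6.18%, above the 1.14 to 4.12% that spans the central 95% of random placements. With the list split into 4 near-equal parts, the share was 10.6% in part 2. It was 4.59% in part 3 (Wilson 95% interval 2.51 to 8.24%, permutation p = 0.11 against random placement), so part 3 alone was not told from random. In part 4 it was 7.76% (Wilson 95% interval 4.90 to 12.1%, permutation p = 0.002). The intervals of parts 3 and 4 overlap and their difference was not tested, so a steady fall is neither shown nor excluded. A candidate explanation that stays open is that the list was sorted by a measure of strength, which the 3 deposited columns do not hold. Stretches of the list ran by chromosome and position, however. Places 759, 760, 761 and 762, for example, started at 18521535, 33608952, 34996944 and 47183586 on chromosome 11. Within such a stretch the place follows position, so the borders between the parts need not follow strength. In the mouse list the median width fell over 4 such parts, from 1365 to 616, 452 and 381 bp. No biological explanation was tested.

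Peaks outside the main chromosomes entered no comparison. KG1a had 4 peaks on unplaced scaffolds, in places 15, 28, 71 and 135 of the list. The mouse list had 91 peaks on 27 unplaced scaffolds. The mouse list also had 4 peaks on the mitochondrial genome, 851, 757, 4123 and 4161 bp wide, between positions 71 and 14999. Like the rest of the list they came from the ChIP library against its input. Whether they reflect ATF4 binding or enrichment unrelated to it was not tested, and the same question holds for the other mouse peaks. The scaffold and mitochondrial peaks are listed because they lie outside the chromosomes compared, and no further control level was at hand for them.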

How the results depend on the processing

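The share of peaks inside genes with its alternatives, the shift by up to 500 kb, the deposited order, the count of genes with a peak inside, the length-matched lists and the density on mouse chromosome X with its alternatives were chosen after the data were seen; the others before. The excess of KG1a peaks near gene ends kept its direction and its p of 0.002 under the 6 alternatives run, with ratios from 1.85 within 5 kb to 7.05 in the first 25% of the list. The tRNA synthetase list stayed past the threshold under the 7 alternatives run, with adjusted p from 2.3e-07 to 0.0030. The lowest came from the first 25% of the deposited order, which was chosen after the data were seen. The highest came from the length-matched lists, where the p before adjustment was the smallest that 10000 lists can give. Among the settings with Fisher's exact test the highest adjusted p was 0.0018. The stress response list also stayed past the threshold under the 7 alternatives, with adjusted p from 0.00014 to 0.039. The amino acid synthesis list did not. It had 1 gene within 500 bp (adjusted p = 0.17), 2 genes by nearest gene within 50 kb (adjusted p = 0.15) and 2 genes when peaks inside genes were counted (adjusted p = 0.12, each by Fisher's exact test). With 500 bp MTHFD2 was lost, and in the other settings more genes had a peak, 503 and 489 of 20037 in place of 102. The excess of peaks inside genes fell to a ratio of 1.11 in the widest 25% (p = 0.20) and 1.04 with shifts (permutation p = 0.27). The shift compares each peak with its own gene-rich or gene-poor surroundings. For the widest 25% the cause was not tested. Taking the widest 25% leaves 218 KG1a and 20772 mouse peaks by construction. Of the named genes, MTHFD2, PFKFB4 and APOA1 had no peak within 500 bp, and SLC7A11, TARS1, PFKFB4 and APOA1 had none in the widest 25%. SLC7A11 and PFKFB4 had none in the first 25% of the deposited order, and the PFKFB4 peak went to another gene when only the nearest was counted. The unknown depth limits every count, since a deeper library gives more peaks. Other settings foreseen for motif patterns, flanking controls, transcript starts, promoter CpG content and genes shared between the lists were not run, as they need a genome sequence, gene strands or a mouse annotation. No replicate could be left out and no paired analysis was possible because each group has 1 library.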

Other observations

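The genes outside the fixed lists and the tests in this part were chosen after the data were seen. The genes picked in this way form no tested group. Of the 3 subunits of the translation initiation factor eIF2, EIF2S2 had a peak with its centre 17 bp inside the high-coordinate end (chromosome 20, 34111981 to 34112472). EIF2S3 had one 354 bp outside its low-coordinate end (chromosome X, 24054386 to 24054819). The nearest peak to EIF2S1 lay 614 kb away. MTOR, the kinase that couples amino acid supply to growth, had a peak 366 bp outside its high-coordinate end (chromosome 1, 11262693 to 11263141). EIF4EBP1, a repressor of translation initiation from the fixed stress list, had one 1007 bp inside its low-coordinate end, just beyond the 1 kb limit. PCK2, a mitochondrial enzyme that makes phosphoenolpyruvate, had a peak 180 bp from a gene end. CSF3, THOC1, MAPK14, SH2B3 and MYC had peaks 296, 100, 422, 698 and 895 bp from a gene end. Their places in the list were 5, 38, 728, 26 and 127 of 873. Those of EIF2S2, EIF2S3, MTOR and PCK2 were 224, 19, 511 and 18.

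Several genes of the fixed lists had a peak inside the gene but further than 1 kb from its ends. The ATF3 peak, at chromosome 1, 212608462 to 212608889, was in place 22 of the list and 12.1 kb from the nearer end. SLC3A2, the heavy chain partner of SLC7A11, had one 7.16 kb from an end, and HK2, a hexokinase, one 26.4 kb from an end. KLHL24, PDK1 and MYB had peaks 2.70, 70.3 and 17.4 kb from an end. The SLC3A2, HK2, KLHL24, PDK1 and MYB peaks were in places 35, 47, 368, 719 and 872 of the list. With peaks inside genes counted, stress response regulators had 5 of 21 members with a peak (adjusted p = 0.0016), and hypoxia and glycolysis genes had 3 of 19 (adjusted p = 0.052, both by Fisher's exact test). The autophagy genes ATG2A and ATG4D, outside the fixed list, had peaks 889 and 758 bp inside a gene end, in places 478 and 732.

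The low number of KG1a peaks on chromosomes 5 and X is a pattern to look at again. A low number of coding genes is argued against as the whole cause. Chromosomes 4, 8, 13 and 18 have fewer coding genes per Mb (2.96 to 4.93) than chromosome 5 (4.98) and X (5.44), yet together had 159 peaks where length gives 152 (ratio 1.05, exact 95% interval 0.90 to 1.20). The interval for chromosome 5 was 0.31 to 0.70. Fewer copies of these chromosomes in the cell line may account for it, but the data do not decide this. Peaks within 5 kb of gene ends numbered 5 where the number of coding genes gives 15.1 (ratio 0.33, exact binomial test, p = 0.0042). Both chromosomes were joined in that test after chromosome 5 alone, with 3 against 7.81, had missed the threshold (exact binomial test, p = 0.096). As these chromosomes were picked for their low totals, a low count in part of the same peaks lends that hypothesis no weight. Copy number was not measured here and how well reads map to each chromosome was not tested, so both stay open. The low number on chromosome 5 was not even along it, which the whole-chromosome totals do not show. No listed peak lay between 131373090 and 176539154, and whether this stretch is behind the low total was not tested. The median peak width was 352 bp on chromosome 5 and 347 bp on X, against 341 bp in the whole KG1a list.

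The sparse mouse X chromosome is another such pattern. A single X copy may account for it, but the density ratio of 0.28 to the autosomes does not decide this. X was picked for that low density, and how the number of called peaks follows copy number was not measured. The ratio was 0.23 in the widest 25% and 0.19 in the first 25% of the list. Weaker signal on X, which would leave fewer and narrower peaks above the threshold, is consistent with the median width there, 481 bp, against 521 to 580 bp on autosomes. The reason for a weaker signal, whether copy number, gene content or mapping, was not tested.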
